A study of Mus musculus with 9 samples.

How the data were processed

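The submitters sequenced TruSeq libraries made from Trizol-extracted total RNA of mouse hepatic stellate cells. Their notes name cutadapt for trimming, HISAT2 2.0.4 for alignment to GRCm38 and StringTie 1.2.3 for assembly and quantification. The cutadapt version and whether reads were counted by strand are not given in the sources used here. The deposited values are FPKM (fragment counts scaled to transcript length and library size) for 11051 protein-coding genes in 9 libraries, and every column was used. Identifiers, symbols and positions come from the deposited table. Of its identifiers, 11044 (99.9%) were found in the GENCODE annotation of GRCm38, and 10115 (91.6%) had the same coordinates there.

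Values were converted to log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, which left 10368 genes and set aside 683. Log2 fold changes are differences of group means on this scale, so folds of genes near or below 1 FPKM are smaller than the ratio of their FPKM means. Group values are FPKM means ± SD with n = 3.

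The model had a mean per group and was fitted with limma 3.58.1 in R 4.3.3, with a prior variance that follows the mean level. It left 6 residual degrees of freedom, and the fitted prior added 2.38. The contrasts were KPC exosomes against control exosomes, Panc02 exosomes against control exosomes, both tumour exosomes against control exosomes, and Panc02 against KPC exosomes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, and tests were two-sided. Nothing in the labels says that the libraries came from separate cultures or animals, so each p measures only the spread between these samples.

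Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 28 of 35 lists that had at least 5 tested members. The same test with an estimated correlation, and fry of limma, were run beside it. The lists, the contrasts, the threshold and the rule for named genes were fixed before the data were examined. For each contrast with control the rule names the 12 genes with the largest log2 fold change in each direction among those that passed, with groups that do not overlap and a higher mean of at least 1 FPKM. For the other contrasts it names 8 in each direction, and the 5 with the lowest p in each direction where fewer pass. It adds up to 4 members with the lowest p of each list described, and 18 genes of stellate cell activation and signalling that are given whatever their values. Genes outside the rule were chosen after their values were seen, and the text says so where they appear.

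The labels number the libraries 1 to 3 in each group without saying what the numbers stand for. After removal of the group means, libraries with the same number correlated across genes in every pair of groups, at 0.639 to 0.810 for number 1 and 0.243 to 0.511 for numbers 2 and 3. Libraries numbered 2 and 3 of different groups also correlated with each other, at 0.299 to 0.613, and 4 of the 9 libraries correlated best with one of their own number. A rule fixed with the contrasts (a correlation above 0.1 in every pair with the same number) was met, so the libraries were paired by number, though the labels state no pairing. The correlations set replicate 1 apart from the others and do not show that numbers 2 and 3 are paired. A fit with the replicate number as a block, with 4 residual degrees of freedom and 3.51 from the prior, was therefore run beside each result. Its values are given beside the named genes, list tests and counts that it changes.

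The steps were tried on simulated values for the 10368 genes with 200 changed genes in each of 3 runs. For KPC exosomes the model found 9.45% of changes of 0.5 log2, 51.7% of changes of 1 and 92.4% of changes of 2. For Panc02 exosomes these shares were 11.4%, 64.2% and 94.4%, with a mean of 0.667 false calls per run in each contrast. With the replicate block the shares were 45.8%, 84.1% and 98.0% for KPC and 50.7%, 90.5% and 98.0% for Panc02, with 7.33 and 9.67 false calls. Both contrasts used the same means and spread, so their shares differ only by the random draws. Genes varied independently around a replicate shift equal in all groups, which favours the block. Without the block, 100 simulations of unchanged groups from the libraries' own deviations gave a median of 0 calls for each source. Their means were 91.7 for KPC and 270 for Panc02, with highest values of 4315 and 5811. The deviations were placed over the libraries at random, so those of several replicate 1 libraries could fall in 1 group. In the data each group holds 1 replicate 1 library, so these means and highest values do not measure false calls in this design. Simulated and random steps used seed 1 or a fixed series of seeds. Other tools were Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.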

Results

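RNA was measured in primary hepatic stellate cells, the vitamin A storing pericytes of the liver that turn into matrix-producing myofibroblasts when activated. The cells came from livers of C57BL/6 mice and received exosomes, small vesicles shed by cells into their medium. The control group received exosomes of primary mouse pancreatic duct epithelial cells. The other groups received exosomes of KPC or Panc02 cells, which are lines of mouse pancreatic adenocarcinoma. Each group held 3 libraries, so there were 9 in all. Cells that received no exosomes were not analysed here, so each contrast compares tumour exosomes with duct cell exosomes. Values are FPKM for 11051 protein-coding genes. The values show no whole-read steps, so the read depth behind them is unknown. FPKM values summed to between 257119 and 307280 per library. Between 9895 and 10270 genes reached 1 FPKM in a library, and the median gene lay at 5.98 to 7.53 FPKM.

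The cells of every group had a mesenchymal profile, with Spp1 (osteopontin) at 378 ± 22.2, Acta2 (smooth muscle actin of myofibroblasts) at 319 ± 21.1, Lox (lysyl oxidase, which cross-links collagen) at 292 ± 40.7, Fn1 (fibronectin) at 262 ± 14.3 and Col1a1 (collagen I) at 107 ± 11.8 FPKM in the control group (SD, n = 3). Of the 18 genes given whatever their values, Des (desmin), Lrat (retinyl ester synthesis) and Igf1 were not among the tested genes. The replicate 1 library of every group stood apart from replicates 2 and 3. Mitochondrially encoded genes made up 26.4%, 33.6% and 28.3% of FPKM in replicate 1 of the control, KPC and Panc02 groups, and 11.2% to 15.9% in the other 6 libraries. The first principal component, 59.0% of the variance, put the replicate 1 libraries at -37.2 to -19.9 and the others at 5.74 to 21.7. The second component, 15.3% of the variance, put the control libraries at -17.4 to -12.9 and the tumour exosome libraries at 2.05 to 12.4. Within groups, Pearson correlations between libraries across genes were 0.940 to 0.990.

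**Figure D1:**
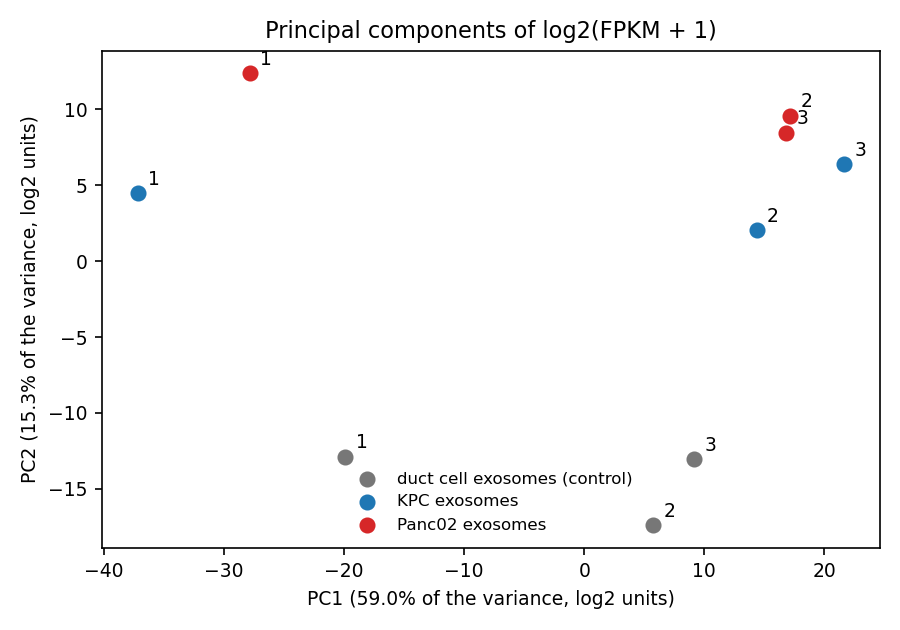
Principal components of log2(FPKM + 1) over the tested genes, with each point 1 library, coloured by exosome source and numbered by replicate. The horizontal axis (59.0% of the variance) parts the replicate 1 libraries, at -37.2 to -19.9, from the rest, and the vertical axis (15.3%) parts the control libraries, at -17.4 to -12.9, from the tumour exosome libraries, at 2.05 to 12.4.

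The first contrast asks how exosomes of KPC cells change stellate cells relative to exosomes of normal duct cells. Among the genes that passed, Adam12, Tnnt2, Pmepa1, Ctgf and Has2 were higher, and Kng2, Dio2, Aldh3a1, C1s1 and C3 were lower. Adam12, a membrane metalloprotease of mesenchymal cells (ENSMUSG00000054555.11, chromosome 7, 133883199 to 134232146), rose from 1.37 ± 0.21 to 7.77 ± 2.32 FPKM (SD, n = 3). Kng2, a kininogen (ENSMUSG00000060459.13, chromosome 16, 22985854 to 23029101), fell from 6.04 ± 0.394 to 1.29 ± 0.423 FPKM. With limma, 13 genes passed as higher and 21 as lower among 10368 tested. In all 34 the 3 KPC libraries lay on 1 side of the 3 control libraries, as in 11.4% of all tested genes. Chance would give 10% if any library could stand in for any other. The replicate 1 libraries stood apart, so the share that chance gives here is not known.

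Among the genes that rose with KPC exosomes, Adam12 had a log2 fold change of 1.86 (SE 0.18, limma adjusted p = 0.0114). Tnnt2, cardiac troponin T (ENSMUSG00000026414.13, chromosome 1, 135836354 to 135852260), rose from 0.258 ± 0.129 to 3.24 ± 0.835 FPKM, a log2 fold change of 1.74 (adjusted p = 0.0247). Pmepa1, a TGF-beta induced protein that restrains Smad signalling (ENSMUSG00000038400.15, chromosome 2, 173224458 to 173276533), rose from 6.16 ± 0.981 to 19.9 ± 6.23 FPKM (log2 1.51, adjusted p = 0.0259). Ctgf, a matricellular growth factor (ENSMUSG00000019997.11, chromosome 10, 24595442 to 24598683), rose from 49.7 ± 1.43 to 98.5 ± 14.5 FPKM (log2 0.96, SE 0.12, adjusted p = 0.0247). Creb3l1, an endoplasmic reticulum bound transcription factor for collagen I, rose by 1.15 log2, C1qtnf3, a secreted C1q and TNF related protein, by 1.12, and Dock8, an exchange factor for Cdc42, by 1.11. Anxa8, a calcium-dependent phospholipid binding protein, rose by 0.98, the hyaluronan synthase Has2 by 0.93, the adhesion molecule Alcam by 0.70, the angiogenic factor Vegfa by 0.70 and the IL-6 family cytokine Il11 by 0.66, with adjusted p from 0.0127 to 0.0363 over these 8 genes. Ctsw, a protease of cytotoxic lymphocytes, also passed (adjusted p = 0.0363), but its exons overlap those of Fibp on the other strand, so its reads are uncertain. Its libraries stood at 0.122, 0 and 0 FPKM with control exosomes and at 3.60, 8.42 and 19.9 FPKM with KPC exosomes.

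Among the genes that fell with KPC exosomes, Kng2 had a log2 fold change of -1.64 (SE 0.15, limma adjusted p = 0.0107). Dio2, the deiodinase that activates thyroid hormone (ENSMUSG00000007682.6, chromosome 12, 90724552 to 90738438), went from 17.2 ± 1.51 to 5.55 ± 1.76 FPKM (log2 -1.51, adjusted p = 0.0259). The aldehyde dehydrogenase Aldh3a1 (ENSMUSG00000019102.10, chromosome 11, 61207537 to 61218421) went from 4.33 ± 0.148 to 1.06 ± 0.183 FPKM (log2 -1.38, SE 0.11, adjusted p = 0.00869). Its relative Aldh1a7 changed by -1.37 log2, from 12.9 ± 1.21 to 4.40 ± 0.757 FPKM. C1s1, a protease of the first complement component (ENSMUSG00000038521.17, chromosome 6, 124530345 to 124542359), went from 51.2 ± 2.44 to 22.6 ± 2.98 FPKM (log2 -1.15, adjusted p = 0.0127), and C3, the central complement protein (ENSMUSG00000024164.15, chromosome 17, 57203970 to 57228136), from 23.2 ± 2.25 to 11.7 ± 0.558 FPKM (log2 -0.93, adjusted p = 0.0127). The glutathione transferases Gstm1 and Gsta4 changed by -1.08 and -0.89 log2, the purine-degrading enzyme Xdh by -0.94, the soluble pattern recognition protein Ptx3 by -0.92, Tcp11l2 by -0.91 and the complement protease C1s2 by -0.87, with adjusted p from 0.0230 to 0.0363 over these 6 genes. Pdgfra, the receptor of platelet-derived growth factor on mesenchymal cells, went from 41.1 ± 3.6 to 24.5 ± 1.59 FPKM (log2 -0.72, adjusted p = 0.0260). Kng2, Aldh1a7, Gstm1, Gsta4, C1s1 and C1s2 have close paralogs, so reads may have been shared among them.

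As fixed lists with KPC exosomes, complement genes were lower by camera, and matrix glycoproteins, collagen processing genes and collagens were higher. Matrix proteases and inhibitors did not pass. Of 6 tested complement genes, C1s1 and C3 passed over all genes and 3 passed as lower when adjusted over the list alone. The complement list had a median log2 fold change of -0.46 (camera of limma, adjusted p = 2.86e-05), with adjusted p = 0.171 with an estimated correlation and adjusted p = 0.00201 by fry (0.0692 with the replicate block). Of 18 matrix glycoproteins and proteoglycans, Has2 passed over all genes and 5 higher and 3 lower members passed adjusted over the list alone (median 0.22, adjusted p = 0.00148, and adjusted p = 0.855 with an estimated correlation). Of 18 collagen processing genes none passed over all genes and 1 passed as higher adjusted over the list alone (median 0.19, adjusted p = 0.000382, and adjusted p = 0.855 with an estimated correlation), with Plod2, a lysyl hydroxylase, at 0.48 log2 (adjusted p = 0.0786, 0.0163 with the replicate block). Of 15 collagens none passed in either way (median 0.21, adjusted p = 0.00864, and adjusted p = 0.855 with an estimated correlation), and Col1a1 stood at 188 ± 52.2 FPKM (log2 0.78, adjusted p = 0.302, 0.0224 with the block). The stellate activation list of 21 genes held 1 higher and 1 lower gene over all genes, Ctgf and Pdgfra, and 3 higher and 2 lower adjusted over the list alone (median 0.11, adjusted p = 0.0290, and adjusted p = 0.855 with an estimated correlation). Of 23 TGF-beta and BMP genes Pmepa1 and Ctgf rose over all genes, and 2 rose and 2 fell adjusted over the list alone (median -0.08, mean 0.05, adjusted p = 0.995). Over all genes and then adjusted over the list alone with the replicate block, 2 and 5 collagens were higher and 0 and 1 lower, and 2 and 6 collagen processing genes were higher. In the same order 5 and 6 glycoproteins were higher and 1 and 4 lower, 4 and 8 activation genes higher and 2 and 2 lower, 2 and 6 TGF-beta genes higher and 3 and 5 lower, and 3 and 3 complement genes lower. The collagens had adjusted p = 0.0613 without control replicate 1 and 0.275 without KPC replicate 3. The activation list had 0.0515 and 0.142 without control replicates 1 and 3, and 0.0520 and 0.0568 without KPC replicates 1 and 3. In the replicate 1 libraries collagens and collagen processing genes had lower levels than in replicates 2 and 3, by medians of -0.43 and -0.47 log2.

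Metabolic lists also passed camera for KPC exosomes. Of 25 glycolysis and hypoxia genes Vegfa passed over all genes and adjusted over the list alone (median 0.13, camera of limma adjusted p = 2.86e-05, and adjusted p = 0.855 with an estimated correlation). Of 23 cholesterol synthesis genes none passed in either way (median 0.17, adjusted p = 0.000164, and adjusted p = 0.855 with an estimated correlation), with Nsdhl at 0.23 log2 (adjusted p = 0.503). Of 24 unfolded protein response genes none passed in either way (median 0.08, adjusted p = 0.0290, and adjusted p = 0.855 with an estimated correlation). Of 43 ribosomal protein genes none passed in either way, with all 43 below 0 (median -0.12, adjusted p = 0.0206, and adjusted p = 0.855 with an estimated correlation). Higher genes with the replicate block, over all genes and then adjusted over the list alone, were 2 and 6 for glycolysis and hypoxia and 0 and 1 for cholesterol synthesis. For ribosomal proteins the adjusted p was 0.265 without the replicate 1 libraries, 0.0760 without control replicate 1, and 0.329 and 0.107 without KPC replicates 1 and 3. The unfolded protein response had 0.0613 without control replicate 1, and 0.0999 and 0.171 without KPC replicates 2 and 3. Of the 13 mitochondrially encoded genes none passed in either way, with a median of -0.09 (adjusted p = 0.809), and -0.34 with adjusted p = 0.000168 without the replicate 1 libraries. Their adjusted p was 0.000215 without KPC replicate 1.

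None of the 15 tested stellate cell genes given whatever their values passed for KPC exosomes (limma). Acta2 stood at 457 ± 68.2 FPKM (log2 0.51, limma adjusted p = 0.371, 0.0404 with the block) and Col3a1 (collagen III) at 31.0 ± 9.19 FPKM (log2 0.58, adjusted p = 0.682). Lox was at 0.43 log2, Ccl2 (a monocyte attractant) at 0.37, Timp1 (a metalloprotease inhibitor) at 0.29, Fn1 at 0.23, Tgfb1 at 0.10, Mki67 (a proliferation marker) at 0.10, Mmp2 (gelatinase) at 0.08, C1qbp at 0.02, Pdgfrb at 0.02, Cd44 (the hyaluronan receptor) at -0.08, Spp1 at -0.11 and Il6 at -0.44, none past the threshold.

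No KPC call was kept when 1 control library alone was left out. Without control replicate 1, 2 or 3 no gene passed in either direction, against 678 genes at an unadjusted p under 0.05 with all 9 libraries, and Aldh3a1 had adjusted p = 0.0543, 0.0611 and 0.084. The count was 2 higher and 5 lower without KPC replicate 2, 1 and 3 without KPC replicate 3, 3 and 5 without Panc02 replicate 2, and 2 and 6 without Panc02 replicate 3. With the replicate block 61 genes were higher and 113 lower, and without the 3 replicate 1 libraries 115 and 84. Both of these fits kept all 34 KPC calls, though the second also lacks control replicate 1. Equal library totals gave 2 and 4. No gene passed with control and KPC libraries alone. The number of lists past camera was 9, and 5 without control replicate 1 or without KPC replicate 3.

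The second contrast asks the same question for exosomes of Panc02 cells. The genes that passed for KPC exosomes passed in the same direction, and further genes passed as well, among them the muscle actin Acta1 and the elastic fibre protein Mfap4 as higher and the cytokine Il6 as lower. Adam12 rose to 11.1 ± 1.1 FPKM, Pmepa1 to 31.1 ± 0.591 FPKM and Ctgf to 134 ± 7.37 FPKM (SD, n = 3). Dio2 fell to 3.90 ± 0.894 FPKM, Aldh3a1 to 0.618 ± 0.155 FPKM and C3 to 11.0 ± 0.416 FPKM. With limma, 45 genes passed as higher and 60 as lower among 10368. In all 105 the 3 Panc02 libraries lay on 1 side of the 3 control libraries, as in 16.1% of all tested genes. The 10% for libraries that could stand in for each other is again no sure guide, given the replicate 1 shift.

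**Figure D2:**
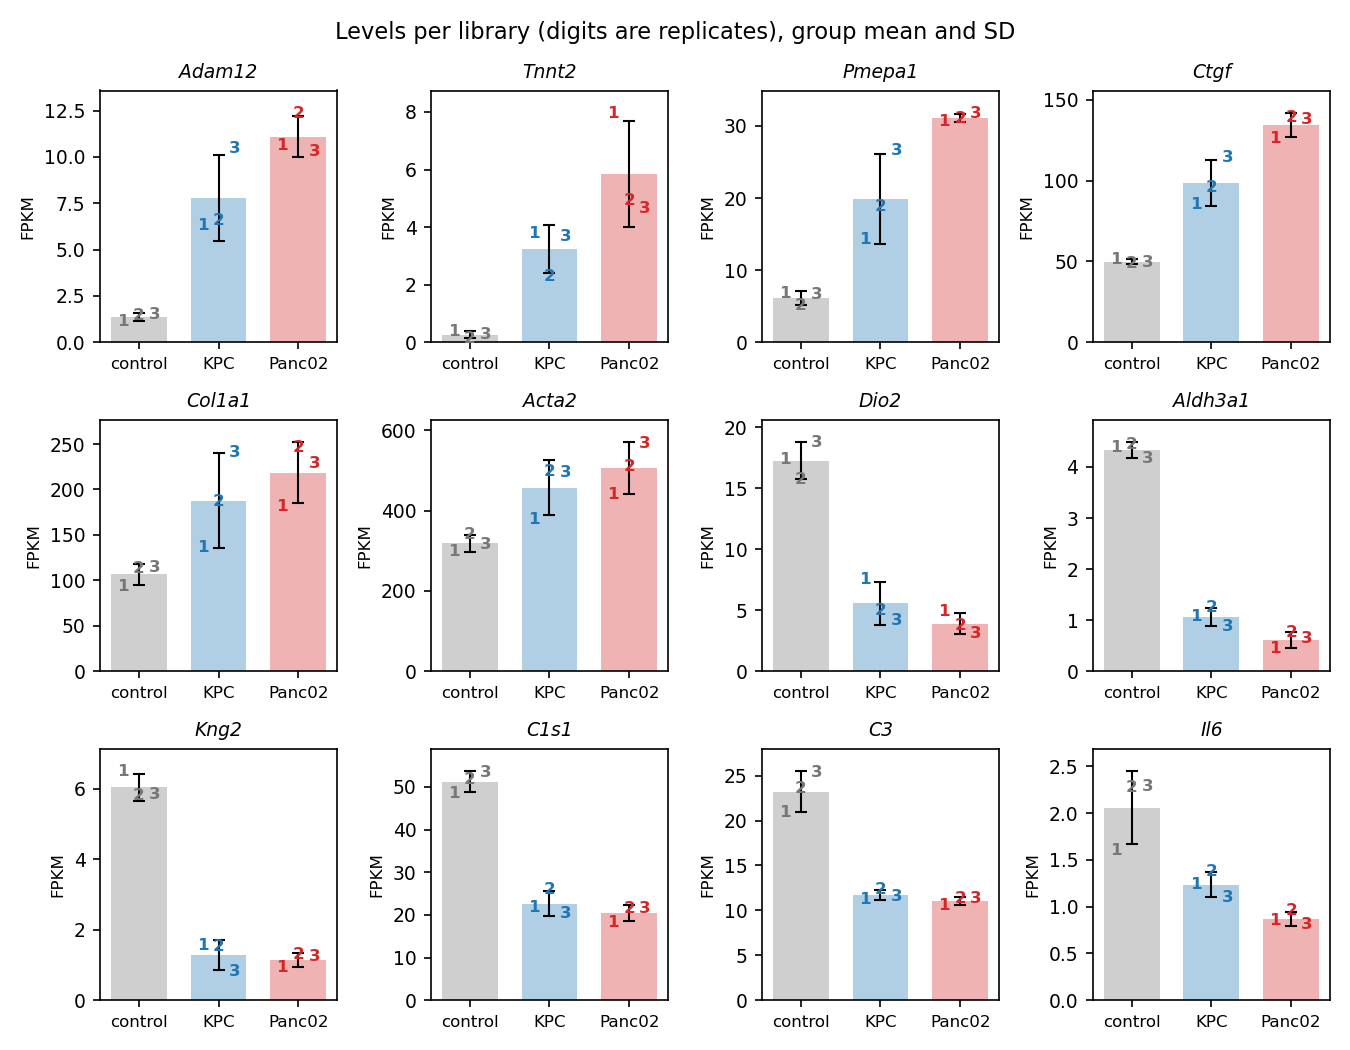
FPKM of 12 genes, with bars for group means, error bars for SD (n = 3) and digits for the replicate number of each library, coloured by exosome source, on linear axes that start at 0. Adam12 rises from a mean of 1.37 with control exosomes to 7.77 with KPC and 11.1 with Panc02 exosomes, and C3 falls from 23.2 to 11.7 and 11.0.

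Tnnt2 rose by 2.42 log2 with Panc02 exosomes, Adam12 by 2.35 (SE 0.18), Pmepa1 by 2.17, Anxa8 by 1.63, Creb3l1 by 1.44, C1qtnf3 by 1.42, Ctgf by 1.41 and Dock8 by 1.41 (limma adjusted p from 0.00284 to 0.00454). Acta1, skeletal muscle actin, rose from 0.563 ± 0.0595 to 7.65 ± 3.73 FPKM (log2 2.35, adjusted p = 0.0485), though reads shared with the other actins leave its level uncertain. Has2 rose by 1.31 log2 and Vegfa by 0.95, and Il11 by 0.72 (adjusted p = 0.00906). Igfbp7, an IGF binding protein, rose from 10.4 ± 2.56 to 30.8 ± 6.45 FPKM (log2 1.49, adjusted p = 0.0244), and Aspn (asporin, a small leucine-rich proteoglycan) from 10.9 ± 1.4 to 32.4 ± 8.41 FPKM (log2 1.47, adjusted p = 0.0321). Mfap4, an elastic fibre protein, passed as higher (adjusted p = 0.0255), with control libraries at 0.12, 0.06 and 0 FPKM and Panc02 libraries at 2.48, 1.23 and 2.62 FPKM. The exons of Igfbp7, Aspn and Mfap4 overlap genes on the other strand, so their levels are uncertain, as is that of Ctsw, at 10.6, 19.0 and 17.8 FPKM with Panc02 exosomes (adjusted p = 0.00859). Exons of other named genes overlap annotated genes that the deposited table lacks, so the same limit may hold for them. Among these are Ctgf, Has2, Dio2, Pdgfra, C1s1, Lox and Fn1 on the other strand and Spp1 on the same strand. With the block Igfbp7 (log2 1.07) and Aspn (log2 1.19) also passed for KPC exosomes, at adjusted p = 0.0155 and 0.00967, against 0.154 and 0.137 without it.

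Among the genes lower with Panc02 exosomes, Dio2 changed by -1.91 log2, Aldh3a1 by -1.72, Kng2 by -1.72, Aldh1a7 by -1.45, C1s1 by -1.29, Xdh by -1.16, Ptx3 by -1.15, Gsta4 by -1.06 and Gstm1 by -1.02 (limma adjusted p from 0.00140 to 0.0272), and C3 had adjusted p = 0.00335. Ogn (osteoglycin, a small proteoglycan) went from 16.6 ± 0.358 to 6.79 ± 1.07 FPKM (log2 -1.19, adjusted p = 0.0251). Id2, a transcriptional inhibitor induced by BMP signalling, went from 22.8 ± 0.374 to 10.2 ± 0.705 FPKM (log2 -1.08, adjusted p = 0.00859). The steroid reductase Akr1c18 went from 39.5 ± 3.22 to 18.8 ± 2.03 FPKM (log2 -1.03, adjusted p = 0.0255). Pdgfra was at -0.81 log2 (adjusted p = 0.00859). With the block Ogn (log2 -0.89) and Id2 (log2 -0.83) also passed for KPC exosomes, at adjusted p = 0.0261 and 0.0224, against 0.137 and 0.0525 without it.

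The lists of matrix glycoproteins, collagen processing genes, collagens and activation genes were higher with Panc02 exosomes by camera, while matrix proteases and inhibitors did not pass. Of 18 matrix glycoproteins 5 rose and 1 fell over all genes, and 9 rose and 3 fell adjusted over the list alone (median 0.38, camera of limma adjusted p = 0.000206, and adjusted p = 0.645 with an estimated correlation). Fbn1 (fibrillin, whose exons overlap a gene on the other strand) was at 1.12 log2 and Bgn (biglycan) at 0.91, with adjusted p = 0.0147 and 0.0234. Of 18 collagen processing genes Plod2 rose over all genes and 4 rose adjusted over the list alone (median 0.30, adjusted p = 3.09e-05, and adjusted p = 0.768 with an estimated correlation), with Plod2 at 0.52 log2. Of 15 collagens none passed over all genes and 4 rose adjusted over the list alone (median 0.38, adjusted p = 0.000212, and adjusted p = 0.768 with an estimated correlation). Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) stood at 218 ± 33.5 FPKM (log2 1.02, adjusted p = 0.0755, 0.00407 with the block) and Col5a2 at 0.90 log2 (adjusted p = 0.0795, 0.00756 with the block). Of 21 activation genes 2 rose and 1 fell over all genes, and 8 rose and 2 fell adjusted over the list alone (median 0.22, adjusted p = 0.00279, and adjusted p = 0.768 with an estimated correlation). The smooth muscle actin Actg2 was at 1.17 log2 (adjusted p = 0.0451). Over all genes and then adjusted over the list alone with the replicate block, 5 and 8 collagens were higher and 0 and 1 lower, and 6 and 9 collagen processing genes were higher. In the same order 8 and 10 glycoproteins were higher and 3 and 4 lower, and 8 and 11 activation genes higher and 2 and 3 lower.

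Complement was lower as a list with Panc02 exosomes, with 3 of 6 genes lower over all genes and adjusted over the list alone and all 6 below 0 (median -0.58, camera of limma adjusted p = 1.17e-05). It had adjusted p = 0.141 with an estimated correlation and adjusted p = 0.000768 by fry, and C1ra, another protease of the first component, was at -0.90 log2 (adjusted p = 0.0272). C1qbp, also on the complement list, lay near 0 and stood at 0.022 log2 with equal library totals. Of 20 cytokines and NF-kB targets 1 rose and 1 fell over all genes, and 2 rose and 5 fell adjusted over the list alone (median -0.15, adjusted p = 0.133). Il6 fell from 2.05 ± 0.390 to 0.871 ± 0.0761 FPKM (log2 -0.70, adjusted p = 0.0321). Of 9 chemokines 1 rose and 2 fell over all genes and adjusted over the list alone (median 0.19, adjusted p = 0.956), with Ccl17 at 1.26, Cxcl5 at -0.77 and Cxcl1 at -0.53 log2. Of 23 TGF-beta and BMP genes 2 rose and 2 fell over all genes, and 6 rose and 4 fell adjusted over the list alone (median 0.06, adjusted p = 0.370). The 4 over all genes were Pmepa1, Ctgf, Id2 and Smad3, a signal transducer of TGF-beta, at -0.55 log2 (adjusted p = 0.0255). Of 18 integrins and adhesion genes 2 rose over all genes, and 4 rose and 1 fell adjusted over the list alone (median 0.15, adjusted p = 0.0233, and adjusted p = 0.768 with an estimated correlation). The 2 over all genes were Ncam1, a neural adhesion molecule, at 0.95 log2 and Itgb3, the integrin beta 3 chain, at 0.89. The integrin list had adjusted p = 0.0846 with the block, 0.113 without the replicate 1 libraries, 0.0742 without control replicate 3 and 0.0715 without Panc02 replicate 1. With the block, over all genes and then adjusted over the list alone, 2 and 4 cytokines and NF-kB targets were higher and 2 and 7 lower, 2 and 3 chemokines higher and 2 and 2 lower, 6 and 7 TGF-beta genes higher and 4 and 6 lower, and 4 and 8 integrins higher and 0 and 3 lower.

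Of 25 glycolysis and hypoxia genes Vegfa rose over all genes with Panc02 exosomes and 4 rose adjusted over the list alone (median 0.17, camera of limma adjusted p = 4.91e-05, and adjusted p = 0.768 with an estimated correlation). Of 23 cholesterol synthesis genes none passed in either way (median 0.19, adjusted p = 0.00235, and adjusted p = 0.768 with an estimated correlation), with Nsdhl at 0.30 log2. Of 24 unfolded protein response genes none passed in either way (median 0.13, adjusted p = 0.0314, and adjusted p = 0.787 with an estimated correlation). Of 43 ribosomal protein genes none passed in either way, with 39 below 0 (median -0.11, adjusted p = 0.0398, and adjusted p = 0.870 with an estimated correlation). With the block, over all genes and then adjusted over the list alone, 4 and 6 glycolysis and hypoxia genes, 1 and 6 cholesterol synthesis genes and 1 and 3 unfolded protein response genes were higher. Quantile scaling gave the ribosomal list adjusted p = 0.0590. Without the replicate 1 libraries the ribosomal list had adjusted p = 0.533, and 0.117 and 0.0688 without control replicates 1 and 2, and 0.559 and 0.210 without Panc02 replicates 1 and 2. The unfolded protein response had 0.0695 without control replicate 1, and 0.0679 and 0.0970 without Panc02 replicates 2 and 3. None of the 13 mitochondrially encoded genes passed in either way, with a median of -0.24 (adjusted p = 0.337, 0.0425 with the block, and adjusted p = 0.829 with an estimated correlation and the block), and -0.40 with adjusted p = 0.000175 without the replicate 1 libraries. Their adjusted p was 0.0485 without control replicate 3 and 0.000864 without Panc02 replicate 1. Of 20 NRF2 target and detoxification genes, Gstm1 and Gsta4 fell over all genes and adjusted over the list alone for both exosome sources, with a list median of 0.00 and mean of -0.18 for KPC (adjusted p = 0.201) and a median of -0.05 for Panc02 (adjusted p = 0.183). With the block 1 NRF2 gene was higher and 3 lower adjusted over the list alone for Panc02 exosomes.

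Among the genes given whatever their values, Il6 passed for Panc02 exosomes. Acta2 stood at 507 ± 63.8 FPKM (log2 0.66, limma adjusted p = 0.102, 0.00860 with the block), Lox at 0.68 log2 (adjusted p = 0.136, 0.0171), Col3a1 at 0.75 (adjusted p = 0.268, 0.0134), Fn1 at 0.49 (adjusted p = 0.283, 0.0434) and Ccl2 at 0.41 (adjusted p = 0.852, 0.0472), the second value of each with the block. Timp1 was at 0.38 log2, Tgfb1 at 0.22, Mmp2 at 0.20, Pdgfrb at 0.16, Cd44 at 0.01, Mki67 at 0.01, C1qbp at -0.01 and Spp1 at -0.11, none past the threshold.

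The Panc02 count was 62 higher and 64 lower without KPC replicate 1 and 44 and 45 without KPC replicate 3. It fell with each other library left out, to 20 higher and 33 lower without control replicate 1, 13 and 13 without control replicate 2, 11 and 12 without control replicate 3, 29 and 34 without KPC replicate 2, 19 and 28 without Panc02 replicate 1, 14 and 14 without Panc02 replicate 2, and 22 and 24 without Panc02 replicate 3. The genes named above that passed in each of the 9 leave-one-out fits were Adam12, Tnnt2, Pmepa1, Creb3l1, C1qtnf3, Dock8, Anxa8, Ctgf, Has2, Vegfa, Kng2, Dio2, Aldh3a1, Aldh1a7, C1s1, Xdh, C3 and Ptx3. With the replicate block 192 genes were higher and 248 lower, and without the 3 replicate 1 libraries 273 and 215. Equal library totals gave 23 and 23.

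**Figure D3:**
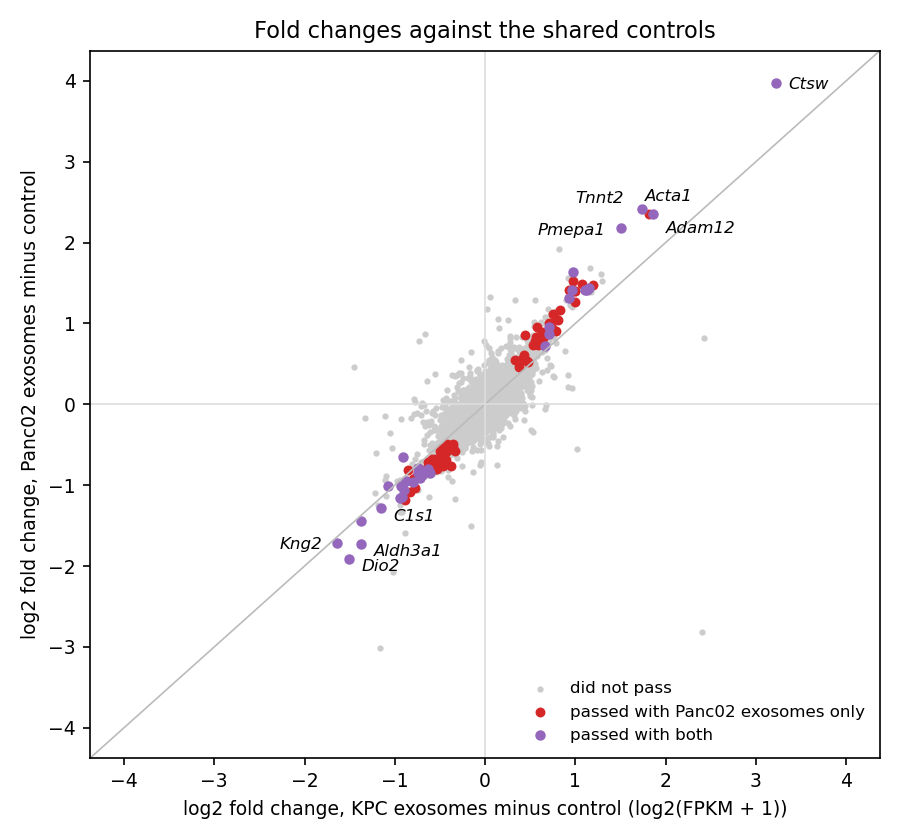
Log2 fold change against control exosomes for KPC (horizontal axis) and Panc02 exosomes (vertical axis), with each point 1 of the 10368 tested genes, coloured by whether it passed for both sources, for Panc02 alone or for neither. All 34 genes that passed for both lie in the same direction, 13 higher and 21 lower.

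Every gene that passed for KPC exosomes also passed for Panc02 exosomes, 13 higher and 21 lower and none in opposite directions, where independent lists would share 0.0564 higher and 0.122 lower genes. Log2 fold changes of the 2 sources correlated at 0.813 across genes, which are not independent replicates, and 82.5% of genes had the same sign. Both contrasts use the same 3 control libraries, which alone makes their folds alike. In 100 simulations of unchanged groups the correlation had a mean of 0.527 (-0.913 to 0.973), the covariance a mean of 0.0308 (-0.0316 to 0.144) against 0.0417 observed, and the same sign a share of 69.9% (10.1% to 94.6%), so each observed value lay inside the range simulated without the block. The simulated number of genes passing in both had a median of 0, a mean of 32.4 higher and 8.43 lower, and highest values of 3238 and 843. The simulations without the block let replicate 1 deviations gather in 1 group, while each real group holds 1 replicate 1 library. Their ranges therefore cannot tell whether the agreement exceeds that from the shared controls. With the block 59 genes were higher and 111 lower in both, against 1.13 and 2.70 for independent lists, with no gene passing in both in any simulation. The observed values lay above the ranges simulated with the block, which were 0.390 to 0.639 for the correlation, 0.00934 to 0.0204 for the covariance and 65.5% to 67.5% for the same sign. The simulations with the block drew noise for each gene independently, without the correlation between genes in the data, so their ranges are too narrow. They cannot show agreement beyond that from the shared controls. The 3 control libraries cannot be divided between the contrasts, so part of the agreement may come from them. The shared count was 0 without any 1 of the control libraries, 6 without KPC replicate 2, 4 without KPC replicate 3, and 8 without Panc02 replicate 2 or 3. It was 178 without the 3 replicate 1 libraries.

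The series design sets both tumour exosome groups together against the duct cell exosomes. In this joint contrast 48 genes were higher and 83 lower of 10368 (limma), with the 6 tumour exosome libraries all on 1 side of the 3 control libraries for all 131. The same held for 8.56% of all tested genes, where chance would give 2.38% if any library could stand in for any other, which the replicate 1 shift goes against. Adam12 rose by 2.11 log2 (SE 0.15, adjusted p = 0.00211), Acta1 by 2.08, Tnnt2 by 2.08, Pmepa1 by 1.84, Aspn by 1.33, Anxa8 by 1.31 and Creb3l1 by 1.30. Aldh3a1 fell by 1.55 log2 (SE 0.09, adjusted p = 0.00103), Dio2 changed by -1.71, Kng2 by -1.68, Aldh1a7 by -1.41, C1s1 by -1.22, Xdh by -1.05, Gstm1 by -1.05 and Ogn by -1.04. Ctsw, uncertain for its overlap with Fibp, passed as higher (adjusted p = 0.00587). Il6 was at -0.57 log2 (adjusted p = 0.0367). Col1a1 was at 0.90 (adjusted p = 0.0659, 0.00363 with the block), Acta2 at 0.59 (adjusted p = 0.0887, 0.00735) and Lox at 0.56 (adjusted p = 0.148, 0.0185).

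The same 10 lists as for Panc02 exosomes passed camera there (limma). Complement had a median of -0.52 (adjusted p = 2.94e-05, 0.171 with an estimated correlation, 0.000529 by fry), with 3 of 6 genes lower over all genes and adjusted over the list alone. Collagen processing had a median of 0.26 (adjusted p = 5.61e-05), glycolysis and hypoxia 0.15 (2.94e-05), matrix glycoproteins 0.31 (0.000421), cholesterol synthesis 0.18 (0.000421), collagens 0.29 (0.000828), activation genes 0.16 (0.00785) and the unfolded protein response 0.10 (0.0207). With an estimated correlation adjusted p = 0.771 for the glycoproteins and 0.804 for the other 6. Integrins had a median of 0.12 (adjusted p = 0.0340, and adjusted p = 0.804 with an estimated correlation, 0.140 with the block and 0.0686 with quantile scaling). Ribosomal proteins had a median of -0.12 (adjusted p = 0.0200, and adjusted p = 0.819 with an estimated correlation). Without the replicate 1 libraries integrins had adjusted p = 0.168, ribosomal proteins 0.365 and mitochondrially encoded genes, at 0.451 with all libraries, 0.000101. The mitochondrially encoded genes had 0.00645 without KPC replicate 1 and 0.0281 without Panc02 replicate 1. Over all genes and adjusted over the list alone, 5 and 9 glycoproteins were higher and 1 and 3 lower, and 2 and 5 activation genes were higher and 1 and 2 lower. Higher genes numbered 1 and 4 for collagen processing, 1 and 4 for glycolysis and hypoxia, 2 and 4 for integrins and 0 and 2 for collagens, and no gene of the other 3 lists passed in either way. With the block, in the same order, 6 and 10 glycoproteins were higher and 4 and 4 lower, 6 and 11 activation genes higher and 2 and 3 lower, 5 and 6 collagens higher and 0 and 1 lower, and 3 and 7 integrins higher and 1 and 5 lower. Higher genes then numbered 6 and 9 for collagen processing, 6 and 8 for glycolysis and hypoxia, 3 and 10 for cholesterol synthesis and 1 and 3 for the unfolded protein response. Integrins had adjusted p = 0.134 without control replicate 3, 0.0775 without KPC replicate 1 and 0.0748 without Panc02 replicate 1, and ribosomal proteins 0.0947, 0.0827, 0.121 and 0.0608 without control replicate 1, KPC replicate 1, Panc02 replicate 1 and Panc02 replicate 2. The unfolded protein response had 0.0574 without control replicate 1.

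The gene count of the joint contrast was 71 higher and 90 lower without KPC replicate 1, 22 higher and 37 lower without control replicate 1, 13 and 14 without control replicate 2, 11 and 14 without control replicate 3, 27 and 37 without KPC replicate 2, 33 and 37 without KPC replicate 3, 36 and 50 without Panc02 replicate 1, 22 and 31 without Panc02 replicate 2, and 27 and 35 without Panc02 replicate 3. With the block it was 190 and 282, and without the 3 replicate 1 libraries 448 and 310.

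**Figure D4:**
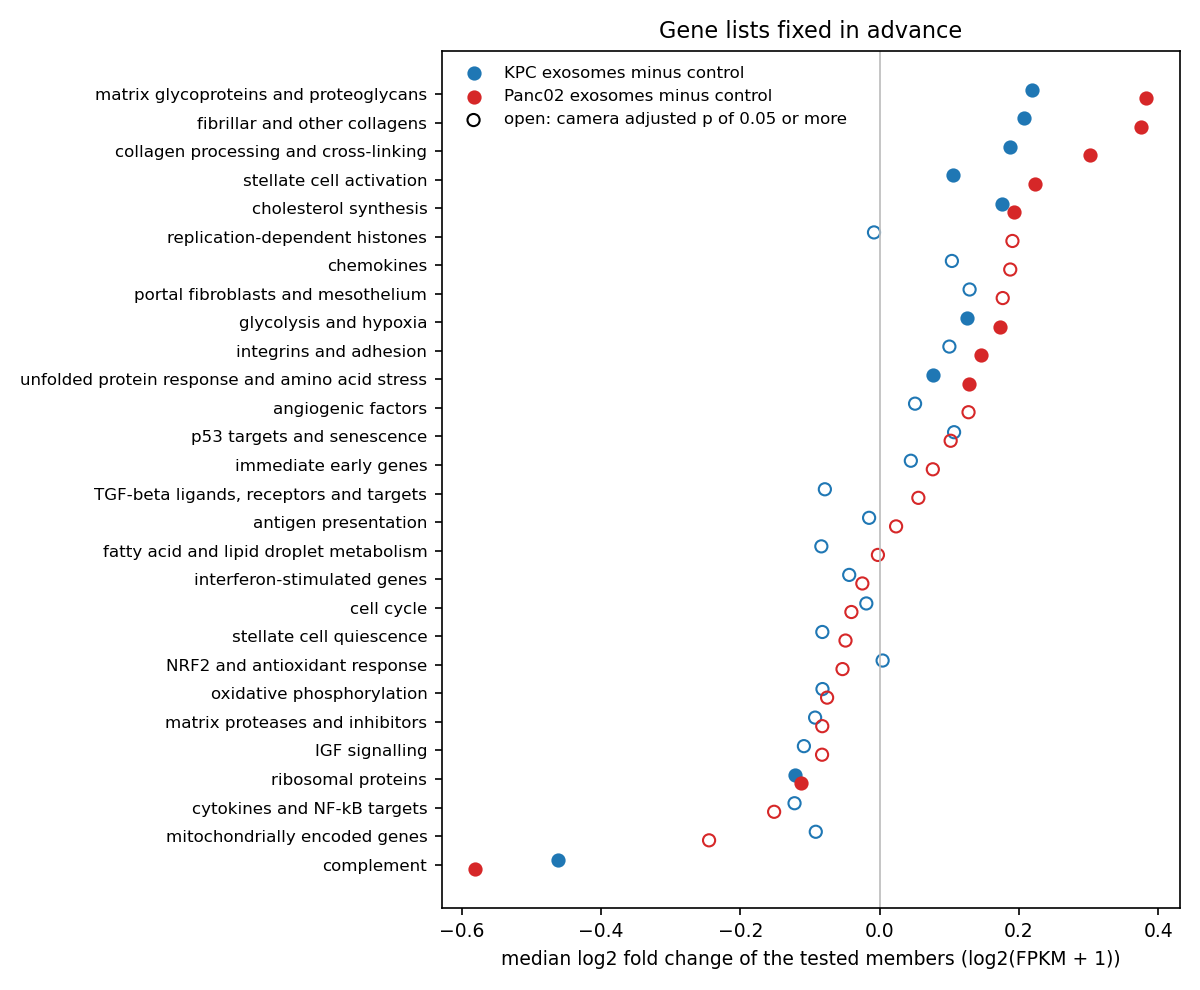
Median log2 fold change of the tested members of each fixed gene list against control exosomes, with KPC in blue and Panc02 in red, filled where the list passed camera at the preset correlation (adjusted p under 0.05). Complement lies lowest among the filled lists, at -0.46 and -0.58, and matrix glycoproteins lie at 0.22 and 0.38.

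The last contrast asks whether the 2 tumour lines differ in their effect. No gene passed in either direction (limma, lowest adjusted p 1), with 86 of 10368 genes at an unadjusted p under 0.05. With the replicate block no gene passed and 260 were at an unadjusted p under 0.05. The genes with the lowest p did not pass. Those with higher values for Panc02 than KPC exosomes were Anxa8 at 0.66 log2, Ctgf at 0.45, Usp33 (a deubiquitinase) at 0.39, Cacul1 at 0.50 and Has2 at 0.39. Those with lower values were Kitl (stem cell factor) at -0.39 log2, Aldh3a1 at -0.35, Cntf (ciliary neurotrophic factor) at -0.43, Zfp788 at -0.89 and Tet2 (a DNA demethylase) at -0.26. The exons of Cntf overlap those of Zfp91 on the same strand, so its reads are uncertain. Among the genes given whatever their values Col1a1 stood at 0.24 log2, Lox at 0.26, Fn1 at 0.26, Col3a1 at 0.17, Acta2 at 0.15 and Il6 at -0.26, none past the threshold. Without KPC replicate 2, Pcdhb22, a protocadherin, was higher (log2 1.45, adjusted p = 0.0137), and without Panc02 replicate 1, Rnf24 was lower (log2 -2.08, adjusted p = 0.00503), both named after their values were seen. With library weights 21 genes were higher and 20 lower, and without the 3 replicate 1 libraries 3 and 5. Of the 28 lists tested, 8 passed camera and 0 passed with an estimated correlation.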

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

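The tests in this part were planned before their results were seen, except the fits without the 3 replicate 1 libraries, which were added after seeing the data. Each gene list here drew attention because it was fixed beforehand and differed between Panc02 and KPC exosomes in a direct test of the difference (camera of limma at the preset correlation). The response score at the end is no such list, since its genes are those that passed in the joint contrast.

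Matrix lists other than that of proteases and inhibitors stood higher with Panc02 than with KPC exosomes. Matrix glycoproteins and proteoglycans had a median difference of 0.12 log2, with 14 of 18 genes above 0 (adjusted p = 0.00205, and adjusted p = 0.729 with an estimated correlation). Collagens had a median of 0.16, with 14 of 15 above 0 (adjusted p = 0.00336, and adjusted p = 0.982 with an estimated correlation), and stellate activation genes 0.12, with 17 of 21 above 0 (adjusted p = 0.00336, and adjusted p = 0.894 with an estimated correlation). Collagen processing genes had a median of 0.10 with all 18 above 0 (adjusted p = 0.0127, and adjusted p = 0.982 with an estimated correlation). TGF-beta ligands, receptors and targets had a median of 0.10, with 16 of 23 above 0 (adjusted p = 0.0229, and adjusted p = 0.982 with an estimated correlation). Integrins and adhesion genes had a median of 0.07, with 12 of 18 above 0 (adjusted p = 0.0229, 0.0895 with the replicate block, and adjusted p = 0.729 with an estimated correlation). Complement stood lower, with a median of -0.12 and all 6 genes below 0 (adjusted p = 0.0147, and adjusted p = 0.729 with an estimated correlation). Replication-dependent histones had a median of 0.22 with all 7 genes above 0 (adjusted p = 0.00504, and adjusted p = 0.729 with an estimated correlation). No gene of these lists passed over all genes or adjusted over the list alone (with the block 1 activation gene, 1 glycoprotein and 1 TGF-beta gene were higher adjusted over the list alone), and fry of limma called 0 of these lists. Scaling by median of ratios gave the integrins adjusted p = 0.0913 and quantile scaling 0.122. Lists past camera numbered 8 with all libraries. Without KPC replicate 1 none of the 8 passed (adjusted p from 0.0512 to 0.749), and without Panc02 replicate 2 only the glycoproteins did (0.0903 to 0.400 for the others). Without Panc02 replicate 3 the glycoproteins and complement passed (0.0608 to 0.285 for the other 6), and ribosomal proteins (0.00583) and oxidative phosphorylation (0.00738) passed as well. Without KPC replicate 3 all 8 passed, with IGF signalling (0.0183), matrix proteases (0.0184), cell cycle and mitochondrially encoded genes as well. The count was 5 without the 3 replicate 1 libraries, where TGF-beta genes had adjusted p = 0.359, complement 0.253 and integrins 0.284. Without KPC replicate 2 complement had 0.151 and integrins 0.329, and without Panc02 replicate 1 integrins had 0.248 and TGF-beta genes 0.0541, with glycolysis and hypoxia at 0.0173 and 0.00787 in these fits. Mitochondrially encoded genes did not pass (adjusted p = 0.225) but had 0.0106 with the replicate block (adjusted p = 0.789 with an estimated correlation and the block, 0.875 by fry with it), and 0.000587, 0.0111 and 0.000199 without KPC replicates 1, 2 and 3 and 4.52e-06 without Panc02 replicate 1.

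The genes that passed against control for both tumour exosomes together moved further with Panc02 exosomes, which may reflect a stronger effect of Panc02 exosomes. A response score, the mean log2 level of the 48 higher genes minus that of the 83 lower genes, was -0.814 ± 0.0747 with control, 0.724 ± 0.230 with KPC and 1.14 ± 0.0170 with Panc02 exosomes (SD, n = 3). The difference of 0.412 between the tumour lines was 0.559 in replicate 1, 0.540 in replicate 2 and 0.137 in replicate 3, and its mean over replicates 2 and 3 was 0.338, which argues against the replicate 1 libraries as its source. Chance differences between libraries stay open, since the exact permutation p was 0.1 (two-sided, 20 assignments), the smallest that 3 against 3 libraries can give, and leaving out any 1 of the 6 libraries gave 0.334 to 0.544. The difference in exosome source that the design names, including the amount of exosomes given, was not tested apart from this and stays open.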

How the results depend on the processing

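The fits without the 3 replicate 1 libraries, with replicate 1 as a batch term, with the GC and length trend removed, and with that removal and the replicate block together were chosen after seeing the data. None of the named results that passed was reversed under any setting run. Their groups do not overlap, so leaving out libraries could not have reversed them. The scalings (median of ratios, equal totals, quantile) moved neither the median of all genes by more than 0.1 log2 nor the share of higher genes by more than 10 points. The share of higher genes among those that passed was 38.2% for KPC, 42.9% for Panc02 and 36.6% for both, but 57.8%, 55.9% and 59.1% without the 3 replicate 1 libraries and 53.8%, 62.2% and 63.3% at a log2 fold change of at least 1. It was 55% for Panc02 with the libraries of the contrast alone, 48.1% and 47.1% for both without control replicate 2 and KPC replicate 3, and 25% for KPC without KPC replicate 3 or Panc02 replicate 3. Counts were not stable. The pseudocounts 0.1 and 0.5, no filter, median-of-ratios and quantile scaling and no mean trend left the counts of genes within 1.5 times. With these 2 scalings the genes behind the counts changed more. Quantile scaling kept 18 of 34 KPC, 76 of 105 Panc02 and 95 of 131 joint calls, and median of ratios kept 22, 82 and 105. The pseudocount 0.1 and the 2 scalings also left the counts of lists within 1.5 times. Lists were not run with the other settings named here, and the scalings changed single list calls at the preset correlation. Quantile scaling gave adjusted p = 0.0590 for ribosomal proteins and 0.0482 for histones with Panc02, and 0.0686 for integrins with both and 0.122 between the lines, where median of ratios gave 0.0913. The GC and length removal gave integrins 0.0483 for KPC and histones 0.0373 for Panc02, and with the block as well histones 0.0167 and integrins 0.0505 for Panc02 and 0.0910 for both. Replicate 1 as a batch term gave integrins 0.0866 for Panc02, 0.134 for both and 0.0872 between the lines, and mitochondrially encoded genes 0.0339 for Panc02 and 0.00690 between the lines. Read depth is unknown, so what it limits could not be measured, and folds of genes near 1 FPKM may rest on few reads. Except where fewer genes, fewer libraries or a higher threshold are named, the cause was not tested.

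With an estimated correlation 0 lists passed for KPC, 0 for Panc02, 0 for both and 0 between the lines, and with fry 1, 1, 1 and 0. At 5 FPKM in 3 libraries, which left 7084 genes, 13 genes were lower for KPC, 37 for Panc02 and 46 for both. Equal totals gave 2 higher and 4 lower for KPC, 23 and 23 for Panc02, 25 and 29 for both and 6 shared. With the libraries of the contrast alone (fewer libraries, and not run for both, which uses all) KPC had 0 higher and 0 lower and Panc02 36 lower. A log2 fold change of at least 1 left 7 and 6 for KPC, 23 and 14 for Panc02 and 19 and 11 for both. Library weights, whose estimation stopped before it converged, gave 824 and 949 for KPC, 412 and 484 for Panc02, 640 and 750 for both, 21 and 20 between the lines and 705 shared. The replicate block gave 61 and 113 for KPC, 192 and 248 for Panc02, 190 and 282 for both and 170 shared, and for the genes named for a single tumour line and for the list tests it changed no other call than those given with the results.

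Without the 3 replicate 1 libraries there were 115 higher and 84 lower genes for KPC, 273 and 215 for Panc02, 448 and 310 for both, 3 and 5 between the lines, 5 lists between the lines and 178 shared genes. Replicate 1 as a batch term gave 94 and 210, 287 and 382, 297 and 462, and 286 shared. With the GC and length trend removed there were 41 and 55, 135 and 140, 132 and 171, and 96 shared, and with the block as well 152 and 221, 358 and 401, 428 and 491, and 352 shared. Leaving out 1 library gave 0 to 14 higher and 0 to 20 lower genes for KPC, 11 to 62 and 12 to 64 for Panc02, 11 to 71 and 14 to 90 for both, 0 to 1 and 0 to 1 between the lines and 0 to 30 shared, with 5 to 10 lists for KPC and 1 to 12 between the lines.

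Of the named genes that did not pass, several near 0 changed sign (log2 fold change). Equal totals put C1qbp at 0.022 for Panc02, and quantile scaling put C1qbp at -0.0041 for KPC and Cd44 at -0.017 and Mki67 at -0.029 for Panc02. Library weights put Mki67 at -0.061, Pdgfrb at -0.11 and Sox9 at 0.060 for KPC, and Cd44 at -0.018 and Mki67 at -0.10 for Panc02. Without the replicate 1 libraries Mki67 stood at -0.12 and Sox9 at 0.039 for KPC, and C1qbp at 0.011, Cd44 at -0.027 and Mki67 at -0.14 for Panc02. With the GC and length trend removed, with or without the block, Pdgfrb stood at -0.011 for KPC. Leaving out 1 library gave for KPC C1qbp -0.017 to 0.058, Mki67 -0.19 to 0.29, Mmp2 -0.13 to 0.36, Pdgfrb -0.25 to 0.26, Sox9 -0.094 to 0.0076 and Tgfb1 -0.13 to 0.43, and for Panc02 C1qbp -0.062 to 0.021, Cd44 -0.013 to 0.039, Mki67 -0.22 to 0.19 and Pdgfrb -0.030 to 0.47. Of 86 named results that passed, 105 of 1256 values under the other settings lost the call and 326 of 774 with 1 library left out, and of 53 that did not pass, 129 of 789 and 4 of 477 values gained one.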

Other observations

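The tests of dilution, carry-over, other splits of the samples, and GC content and length as explanations of the replicate 1 shift were planned before their results were seen, while the fits without replicate 1, the fits with the GC and length trend removed, and the tests of GC content and of a few genes as the whole cause of that shift were chosen after seeing the data.

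None of 41 cell cycle genes, 16 interferon-stimulated genes, 11 antigen presentation genes, 31 oxidative phosphorylation genes and 7 replication-dependent histones passed for KPC or Panc02 exosomes, over all genes or adjusted over the list alone. Among interferon-stimulated genes 1 was higher and 1 lower for Panc02 exosomes over all genes with the replicate block, and adjusted over the list alone 4 were lower for KPC and 1 higher and 3 lower for Panc02. Without the block the 5 lists had camera adjusted p (limma) of 0.995, 0.214, 0.995, 0.362 and 0.910 for KPC and 0.481, 0.337, 0.798, 0.240 and 0.117 for Panc02 exosomes. Without 1 library, oxidative phosphorylation had adjusted p = 0.0165 for Panc02 exosomes (without Panc02 replicate 3) and histones 0.0319 (without KPC replicate 1) and 0.0330 (without Panc02 replicate 1), and histones had 0.0482 with quantile scaling and 0.00435 without the 3 replicate 1 libraries. Of 15 angiogenic factors Vegfa, which the glycolysis and hypoxia list also holds, rose for both sources and Hbegf, an EGF receptor ligand, rose with Panc02 exosomes at 0.61 log2 (adjusted p = 0.0451). Adjusted over the list alone 3 rose and 1 fell with KPC and 4 rose and 3 fell with Panc02 exosomes (camera adjusted p = 0.311 and 0.183). Of 16 matrix proteases and inhibitors the aggrecanase relative Adamts12 rose with Panc02 exosomes at 0.83 log2 (adjusted p = 0.0158), and adjusted over the list alone 1 rose and 3 fell with KPC and 1 rose and 2 fell with Panc02 exosomes (camera adjusted p = 0.203 and 0.486, the latter with a median of -0.08 and a mean of 0.01). Of 11 IGF signalling genes Igfbp7 rose with Panc02 exosomes over all genes, and 1 rose adjusted over the list alone for each source (camera adjusted p = 0.677 and 0.798, the latter with a median of -0.08 and a mean of 0.06). None of 7 quiescence genes passed over all genes, and 1 fell adjusted over the list alone for each source (camera adjusted p = 0.189 and 0.302). With the block, over all genes and then adjusted over the list alone, angiogenic factors had 1 and 3 higher and 0 and 3 lower for KPC and 4 and 4 higher and 2 and 5 lower for Panc02 exosomes. In the same order matrix proteases and inhibitors had 0 and 3 higher and 1 and 7 lower for KPC and 2 and 3 higher and 3 and 6 lower for Panc02, and IGF signalling 1 and 1 higher and 0 and 1 lower for each source. Quiescence genes had 0 and 1 higher and 1 and 1 lower for Panc02.

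No p53 target among 17, fatty acid gene among 23 or immediate early gene among 22 passed over all genes for either source (limma). Adjusted over the list alone none of the p53 targets passed for KPC and 2 rose and 4 fell for Panc02 exosomes (camera adjusted p = 0.809 and 0.859), none of the fatty acid genes passed for KPC and 1 fell for Panc02 (0.189 and 0.370), and of the immediate early genes 1 rose and 1 fell for KPC and 2 rose and 1 fell for Panc02 (0.362 and 0.469). For KPC exosomes 1 of the 20 cytokines and NF-kB targets, Il11, rose over all genes and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.160), and of 9 chemokines none passed over all genes and 1 rose and 2 fell adjusted over the list alone (0.884). Integrins had adjusted p = 0.0666 for KPC exosomes, with none past over all genes and 2 higher adjusted over the list alone, and 0.0360 without control replicate 2 and 0.0247 without KPC replicate 2. NRF2 genes had adjusted p = 0.0338 for KPC exosomes without KPC replicate 2. Over all genes and then adjusted over the list alone with the replicate block, p53 targets had 1 and 1 lower for KPC and 1 and 2 higher and 2 and 4 lower for Panc02 exosomes. In the same order fatty acid genes had 0 and 5 lower for KPC and 0 and 3 higher and 3 and 4 lower for Panc02, and immediate early genes 0 and 2 higher and 0 and 3 lower for KPC and 2 and 3 higher and 1 and 3 lower for Panc02. For KPC the cytokines and NF-kB targets then had 1 and 2 higher and 0 and 4 lower, chemokines 1 and 2 higher and 1 and 2 lower, and integrins 1 and 2 higher and 0 and 1 lower.

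Markers of other cell types were few in the deposited table. Its least expressed row still reached 0.537 FPKM in a library, so genes missing from it may have been left out for low values. It also held only 8 of 25 stellate quiescence genes. The table held none of the T, B and natural killer cell genes, 2 of the neutrophil genes (none tested), 6 of the macrophage genes (4 tested) and 3 of the endothelial genes (2 tested). Macrophage markers had medians of -0.17 with KPC and -0.35 log2 with Panc02 exosomes, with none past over all genes and 1 lower adjusted over the list alone for each source. Endothelial markers had medians of 0.02 and 0.10, with none past in either way. Of the ductal and cholangiocyte markers 5 were in the table and 2 tested, with medians of 0.44 and 0.82, none past over all genes and 1 higher adjusted over the list alone with Panc02 exosomes. The hepatocyte list had 2 tested members, Ass1 (arginine synthesis) at 1.16 and 1.68 log2 and Hp (haptoglobin) at 0.54 and 0.53, with none past over all genes and both higher adjusted over the list alone for each source. Ass1 passed with the replicate block at adjusted p = 0.0292 for KPC and 0.00381 for Panc02 exosomes (limma). The 1 tested gene of pancreatic acinar and islet cells stood at -0.09 and 0.22. Of 8 portal fibroblast and mesothelial genes Mfap4 rose with Panc02 exosomes over all genes, and adjusted over the list alone 1 rose with KPC and 3 rose and 1 fell with Panc02 exosomes (camera adjusted p = 0.326 and 0.337). With the block, over all genes and then adjusted over the list alone, portal fibroblast genes had 1 and 2 higher and 1 and 3 lower for KPC and 2 and 4 higher and 1 and 3 lower for Panc02. For Panc02 ductal markers then had 1 and 1 higher, the acinar gene passed as higher over the list alone, and macrophage markers had 0 and 2 lower.

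The replicate 1 libraries of all 3 groups stood apart, with 5769 of 10368 genes differing from replicates 2 and 3 (1351 higher, 4418 lower, limma), among them Gpatch4 at 1.96 log2 above and Rps2 at -1.91 log2 relative to the others. Gene length explained 1.74% of the variance of this shift across genes, which argues against length bias. GC content explained 35.2% and may account for a part, but 57.1% of the genes still passed with the GC trend removed, which argues against GC content as the whole cause. After median-of-ratios scaling 71.9% of them passed and 5517 genes passed in all, so a few abundant genes, such as the mitochondrial ones (12 of 13 higher, median 1.37 log2), are not the whole cause, and their part stays open. The labels name no batch, day or animal for replicate 1, so no biological explanation was tested.

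The genes that passed with tumour exosomes may reflect a response of the stellate cells to cargo in which tumour and duct cell exosomes differ, which was not tested. Technical explanations were weighed against such a response. Of the 131 genes, 88.5% kept direction and passed with the GC and length trend of each library removed, which argues against that bias. The median log2 fold change of all genes was -0.00561, against -0.638 for the genes that were lower. FPKM is scaled to library size, so dilution that lowered every gene alike would leave this median near 0 as well. Such even dilution would also leave the genes that were lower near 0, so their median of -0.638 argues against it for those genes. Dilution of the cells' RNA by vesicle RNA that holds some genes and not others was not tested and stays open. Tumour epithelial RNA carried over with the vesicles cannot be told apart from a response for the genes that were higher, because only Sox9 and Krt8 of the epithelial list could be tested (median 0.626, with Sox9 at -0.05 for KPC and 0.06 for Panc02 exosomes) and the control exosomes are epithelial too. Krt8 stood at 0.251, 0.127 and 1.27 FPKM with control, 1.74, 1.93 and 1.70 with KPC and 6.54, 2.14 and 2.53 with Panc02 exosomes, while Krt18 lay at 0.399 to 0.762 in all 9 libraries, and Krt19 and Epcam were high in 1 library alone, at 3.89, 0 and 1.01 and at 3.89, 0 and 0.767 with Panc02, against 0.0401 to 0.819 and 0 to 0.519 with KPC and 0 to 0.451 and 0 to 0.378 with control exosomes.

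Other splits of the 6 libraries of a contrast were counted with limma, with the 3 libraries of the other group kept in the fit as a group of their own. Without that group the real split gave 0 genes for KPC and 80 for Panc02, and the other splits were not run that way. For KPC against control 34 genes passed in the real split and at most 1 in the others, with 1 of 10 splits giving as many, and for Panc02 against control 105 passed and at most 1 in the others, again with 1 of 10. For Panc02 against KPC exosomes 0 genes passed (86 at an unadjusted p under 0.05), 10 of 10 splits gave as many, and the highest other gave 1. These 10 splits are too few for a share under 0.05. With the replicate block, among the 4 splits that part every pair, the counts were 174 against at most 1 for KPC, 440 against 0 for Panc02 and 0 against at most 1 for Panc02 against KPC, while the other splits part 1 pair. For both tumour exosomes, fitted as 2 groups, 169 genes passed and 2 of 84 splits gave as many, the other being the 3 replicate 1 libraries against the rest with 5282 genes, which points to that structure of the samples. With the block, 629 genes passed, the highest other of 27 splits with 1 control per replicate number gave 3, and only the real split gave as many. This argues against chance but does not exclude it. It is the smallest share that these splits can give, and they rest on a pairing that the labels do not state.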
